A study of Drosophila melanogaster with 2 samples.

How the data were processed

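Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed with an antibody against GFP on whole Drosophila melanogaster embryos aged 0 to 24 h that expressed the product of CG14014 fused to enhanced GFP. Per the labels, there were 2 biological replicates, chromatin was sheared by sonication and fragments were between 200 and 800 bp long. The labels give 1 group, so no groups were compared. The possible control experiment that the labels name was not used here.

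The data were peak lists that the authors deposited, on genome build dm6 per the file notes deposited with each sample. The aligner and the peak caller are not given in the sources used here. Each peak carried a signal value set by the authors, whose scale is not given in the sources used here, and it served only to describe and rank peaks within a list. The ranked lists also carried the −log10 of the global irreproducible discovery rate (IDR), as the authors deposited it. The global IDR of a peak is the estimated share of irreproducible peaks among that peak and all ranked above it, and not the chance for a single peak. A ranked list and a thresholded list came from each replicate alone, and series lists came from both replicates. The conservative list drew on a ranking of the true replicates and the optimal list on a further ranking of the pooled reads. All thresholded peaks had a global IDR of 0.01 or less. The authors' thresholded lists held fewer peaks than their rankings at that threshold, by 83 for the conservative list and 158 for the optimal list. No file gave read counts, so the depth of each replicate is unknown and no interval rests on it. Intervals of percentages are 95% Wilson intervals over peaks or genes and cover counting error only. Peaks and genes are not independent replicates, so p-values over them do not measure the spread between embryos.

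The conservative list was the main peak set. Peak ends were compared with the lengths of the 7 chromosome arms (2L, 2R, 3L, 3R, 4, X and Y) of the release 6 reference sequence, and none lay beyond an arm. Genes and transcription start sites (TSS) came from Ensembl release 115, with transposable elements left out. A summit was assigned to a promoter (within 500 bp of a TSS of a protein-coding gene), otherwise to an exon, an intron or intergenic sequence. Class shares were compared with the share of non-N bases by exact binomial tests. Replicate lists were compared by overlap of at least 1 bp, and chance overlap came from 100 random placements within each chromosome. Gene lists fixed before the data were examined were tested by two-sided Fisher exact tests, with Benjamini-Hochberg adjustment over the 27 lists. The background was all protein-coding genes, or all genes for the tRNA and snRNA lists. A total of 29 consensus words and all 2080 6-mers (reverse complements collapsed) were counted in windows of 50 bp to each side of the summit. They were compared with a window centred 300 bp to one side of the same summit by exact McNemar tests, with Benjamini-Hochberg adjustment. Conservative peaks had a median width of 330 bp, so this window mostly lay outside the peak. Odds ratios of these tests are ratios of discordant peaks with 0.5 added to each count. Divergent genes had a head-to-head TSS of another protein-coding gene within 500 bp.

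The design, the gene lists, the words and most alternatives were chosen before the data were examined. The rule for named items took the 25 conservative peaks with the highest signal, the CG14014 locus, up to 4 members of each list past an adjusted p of 0.05 and up to 2 of other lists, ranked by promoter signal. For words it took at most 8 that passed, by size of the odds ratio, and the 5 leading 6-mers. The position of summits relative to the TSS, the GC content, the split by signal rank and the comparison of chromosome 4 were added after the data were seen. So were the alternatives with a global IDR of 0.001 or 0.05, with merged peaks, with background windows of the same GC count and, for 6-mers, with promoter windows without a peak.

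The functions were tested on simulated data. With 25% of 3216 simulated summits planted at a TSS, 33.5% were assigned to promoters, against 33.4% implied by the planting. Of 20 simulated peak sets without an effect, 1 gave a p below 0.05. In 20 random draws of genes no list passed. The mitochondrial ribosomal protein list (73 genes), given a 4-fold higher chance to be drawn, was recovered in 20 of 20. Other lists and depletion were not simulated. Genes were drawn independently, so lists of copied or neighbouring genes and peaks shared by 2 genes were not simulated either. A word implanted in 200 windows was found in 200, and none of the other 28 words passed. No 6-mer passed at random positions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.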

Results

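Binding of the CG14014 product tagged with enhanced GFP was mapped in whole embryos aged 0 to 24 h, in 2 biological replicates of 1 group. The question was where in the genome the fusion protein was found. The conservative list of peaks reproducible between the replicates held 3216 peaks with a median width of 330 bp, or 3092 regions after overlapping peaks were merged. The optimal list held 5675 peaks, of which 3088 were identical to conservative peaks (96.0% of these). Replicate 1 alone had 4617 thresholded peaks and replicate 2 had 2737, a ratio of 1.69. Read depth is unknown for both replicates, so the difference in list length could not be set against depth. Coordinates are dm6, and signal values are the authors' own per peak.

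The 25 peaks with the highest signal are described here by gene, and no common function of these genes was tested. The highest signal, 2570.4, belonged to a peak at 3L, 19590460 to 19590779, whose summit was 94 bp upstream of CG14100 (FBgn0036889). It had a signal of 1271 in the ranking of replicate 1 and 1305 in that of replicate 2. The next peak, with a signal of 2449, lay on X at 2703713 to 2704058, 41 bp upstream of Ugalt (FBgn0024994), which encodes a UDP-galactose transporter. A peak at 2R, 15217591 to 15217915, had a signal of 2269 and its summit 141 bp upstream of mRpL41 (FBgn0034001), a protein of the large mitochondrial ribosomal subunit. Another, at 2L, 6612432 to 6612950, had a signal of 2409 and lay in an intron of CG11050 (FBgn0031836), 1031 bp from its nearest TSS.

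A peak with a signal of 1667 lay 128 bp upstream of mRpS10 (FBgn0038307) and within the promoter window of Art3, an arginine methyltransferase gene. A peak with a signal of 1657 lay 100 bp upstream of CenG1A (FBgn0028509) and within the promoter window of mRpS23. The promoter of PNPase (FBgn0039846), a mitochondrial exoribonuclease, had a signal of 1574. The promoter of eIF6 (FBgn0034915), a factor of ribosome assembly, had a signal of 1396, with the summit 102 bp upstream and inside an intron of the neighbouring gene ytr. Single summits lay within 500 bp of a TSS of 2 genes at CG7601 and CIA30 (signal 1787), Tcs5 and CHMP2B (1642), CG5611 and Mtl (1376), CG8320 and Pex11ab (1267), CG13390 and CG17294 (1264), and Elp5 and CG1275 (1186). CG18549 had a signal of 1401 and Gapdh2, a glycolytic enzyme gene, of 1306, both upstream of the TSS.

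The promoter window of the Polycomb group gene ph-p (FBgn0004861) held a peak with a signal of 1635 at X, 2137201 to 2137519, inside an intron, with the summit 499 bp from the TSS. The summit at Chro (FBgn0044324), a chromodomain protein gene, lay in its 5' UTR (3L, 22878747 to 22879047, signal 1318), and the promoter window of Ssl1, a subunit of the general factor TFIIH, shared it. Peaks lay in introns of Adf1 (FBgn0284249, signal 1329), of Tlk (FBgn0283657, 1301) and of Trl (FBgn0013263, 1217), which encodes the GAGA factor. A further intronic peak lay within both HmgZ and HmgD, neighbouring HMG-box protein genes, with a signal of 1596. The remaining peaks of the 25 were in an intron of CG32772 (1350), in an exon of the noncoding gene lncRNA:Vinr with CG4004 as the nearest coding gene (1437), and in intergenic sequence 11913 bp from CG13323 (1196). In all, 17 of the 25 summits were at promoters, 6 in other intronic sequence, 1 in an exon and 1 between genes. Among the 25, 21 were also in the top 25 by the signal of replicate 1 and 22 by that of replicate 2.

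The gene of the tagged protein itself, CG14014 (FBgn0031718, 2L, 5549709 to 5550835, minus strand), overlapped 0 peaks of the conservative, optimal and replicate lists, and 0 peaks of the ranked list of the true replicates. The nearest conservative summit lay 4126 bp from its TSS, in a promoter peak of Oscillin with a signal of 285 (2L, 5546633 to 5546782).

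Promoters held 1569 of the 3216 summits (48.8%, 95% Wilson interval 47.1 to 50.5), against 11.2% of the genome, a 4.36-fold excess. The exact binomial p was too small for double precision. Exons held 3.20% of summits against 20.4% of the genome (0.157-fold, exact binomial test, adjusted p = 8.3e-184). Introns held 36.1% (0.911-fold, exact binomial test, adjusted p = 4.58e-05) and intergenic sequence 11.9% (0.415-fold, adjusted p = 3.95e-116). The promoter share was 64.0% (58.4 to 69.2) among the 300 peaks with the highest signal, 53.7% (50.01 to 57.4) among the next 700 and 45.2% (43.1 to 47.3) among the other 2216. The first and last of these differed (Fisher exact test, p = 8.39e-10).

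**Figure D1:**
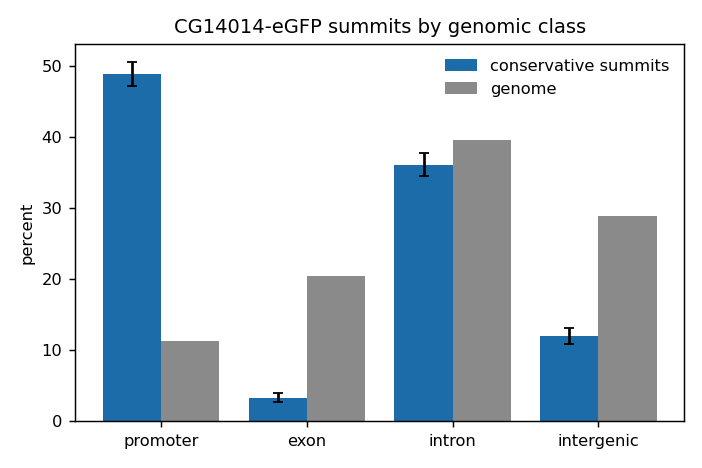
Percent of the 3216 conservative summits (blue, with 95% Wilson intervals) and of the genome (grey) in each genomic class. Promoters hold 48.8% of summits and 11.2% of the genome, and exons hold 3.20% of summits and 20.4% of the genome.

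Promoter summits lay mostly upstream of the TSS. Of 1569, 1293 were upstream (82.4%, interval 80.4 to 84.2, exact binomial test against equal shares, p = 2.86e-157). The median position was 109 bp upstream, and the window from 150 to 100 bp upstream held the most summits, 344. Among the 192 promoter summits of the 300 strongest peaks, 171 were upstream (89.1%, 83.9 to 92.7), with a median of 132 bp upstream.

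**Figure D2:**
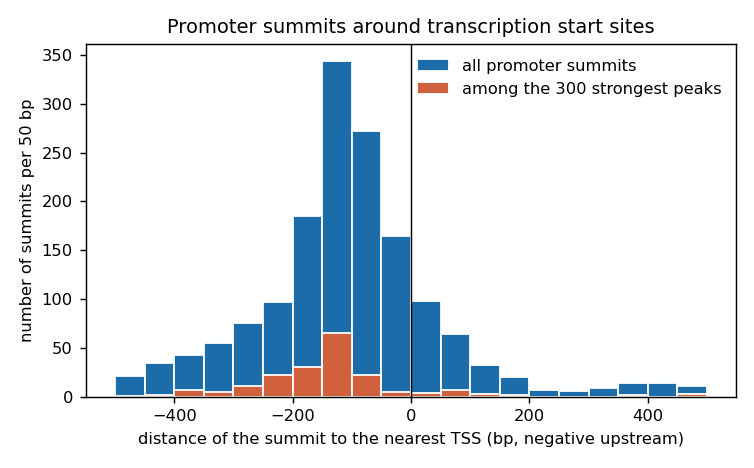
Number of promoter summits per 50 bp by distance to the nearest TSS of a protein-coding gene, negative values upstream, for all 1569 promoter summits (blue) and for those among the 300 strongest peaks (orange). Both distributions have their maximum between 150 and 100 bp upstream, with 344 and 65 summits.

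Genes for cytoplasmic ribosomal proteins had a promoter peak more often than other genes. Of 92 such genes, 54 had one (58.7%, 95% Wilson interval 48.5 to 68.2), among them RpL32 (signal 447), RpL7 (438), RpS27 (393) and RpL23A (343). Of all 13968 protein-coding genes, 2040 had one (14.6%). The odds ratio was 8.51 (Fisher exact test, adjusted p = 3.73e-21), and the list passed in each of the 12 settings, the main one included, with odds ratios from 5.63 in replicate 2 alone to 12.7 in replicate 1 alone. The strongest of these peaks ranked 211, below the mitochondrial peaks at mRpL41 and mRpS10 at ranks 4 and 6. The background of this and the other lists took genes whether or not they were active in these embryos. No expression data and no control experiment were used here. Whether shares above or below the background follow promoter activity was therefore not tested.

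Sensory receptor, tRNA and histone genes had promoter peaks less often. None of 179 odorant, gustatory and ionotropic receptor genes had one (upper limit 2.10%, Fisher exact test, adjusted p = 1.08e-11). Of 295 tRNA genes, 9 had one (3.05%, interval 1.61 to 5.70) against 12.05% of all annotated genes (odds ratio 0.227, Fisher exact test, adjusted p = 4.09e-07). The odds ratio depended on the setting: it was 0.558 (9.49% of tRNA genes) in replicate 1 alone and 0.0361 with promoters of 200 bp, and the list passed in both. The highest signals in this list were at tRNA:Tyr-GTA-1-8 (418), tRNA:Phe-GAA-1-2 (171), tRNA:Val-CAC-2-5 (166) and tRNA:Leu-TAA-2-1 (163). Of 111 replication-dependent histone genes, 0 had one (upper limit 3.35%, Fisher exact test, adjusted p = 3.46e-07). These are copies of a few genes and not independent, so the limit and the p overstate the evidence. Histone and tRNA genes are repeated, and reads from repeats can be lost in mapping or filtering, which the peak lists do not show directly. Fewer than 5 histone genes had a promoter summit even among all ranked peaks of the true replicates. The lack of peaks there thus does not depend on the threshold and does not show a lack of binding.

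The other lists of genes for translation, transcription, chromatin and cell maintenance did not pass the adjusted threshold. Mitochondrial ribosomal protein genes had a promoter peak in 19 of 73 (26.0%, Fisher exact test, adjusted p = 0.061), with mRpL41 (2269) and mRpS10 (1667) the strongest. Translation factors had one in 14 of 53 (Fisher exact test, adjusted p = 0.098), with eIF6 (1396) and eEF1gamma (335). Insulator and architectural protein genes had one in 8 of 24 (33.3%, Fisher exact test, adjusted p = 0.0655), with Chro (1318) and Cp190 (498), and TFIID and general transcription genes in 11 of 37 (adjusted p = 0.0655), with Ssl1 (1318) and TH1 (431). The insulator list did pass in 4 of the 12 settings, among them the list of each replicate alone (Fisher exact test, adjusted p of 0.0125 and 0.0115). The mitochondrial and TFIID lists passed in 2 settings each and the translation factor and germline lists in 1 each. With only the nearest TSS per peak, mitochondrial ribosomal protein genes fell to 9 of 73 (odds ratio 1.21) and TFIID genes to 4 of 37 (1.04). The counts were 5 of 22 for the Polycomb group, with ph-p (1635) and E(z) (399), and 7 of 30 for the trithorax group and chromatin remodellers, with brm (855) and Ino80 (303). They were 8 of 48 for proteasome subunits, with Rpn3 (181), 10 of 54 for cell cycle and DNA replication, with Dp (419), and 9 of 32 for the germline and piRNA pathway, with orb (261). Heat shock protein genes had 6 of 22, with Hsp27 (424) and Hsp83 (258), and snRNA genes 2 of 32, with snRNA:U1:95Ca (136).

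None of the lists of developmental genes differed from the background past the threshold, and their shares lay on both sides of its 14.6%. No promoter peak was found at the 8 Hox genes (upper limit 32.4%), the 16 gap and pair-rule genes, the 20 epidermis and cuticle genes, the 17 hemocyte and extracellular matrix genes or the 20 antimicrobial peptide genes. No lower count was possible in these lists, and their p before adjustment was still 0.103 to 0.613 (Fisher exact test). The lists were therefore too small for a depletion to pass, and the tests do not show its absence. Neural development genes had 1 of 31, at elav (signal 709, Fisher exact test, adjusted p = 0.205), which encodes a neuronal RNA-binding protein. Dorsoventral patterning had 1 of 19, at cact (204), and the tracheal system 1 of 15, at trh (191). Wingless and Hedgehog genes had 2 of 26, at sgg (533) and nkd (373), and muscle and mesoderm genes 3 of 27, including tin (390) and sls (314). Gut and endoderm genes had 2 of 13, at bowl (413) and tin, and the Notch pathway and E(spl) complex had 4 of 21 (19.05%), including numb (373).

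**Figure D3:**
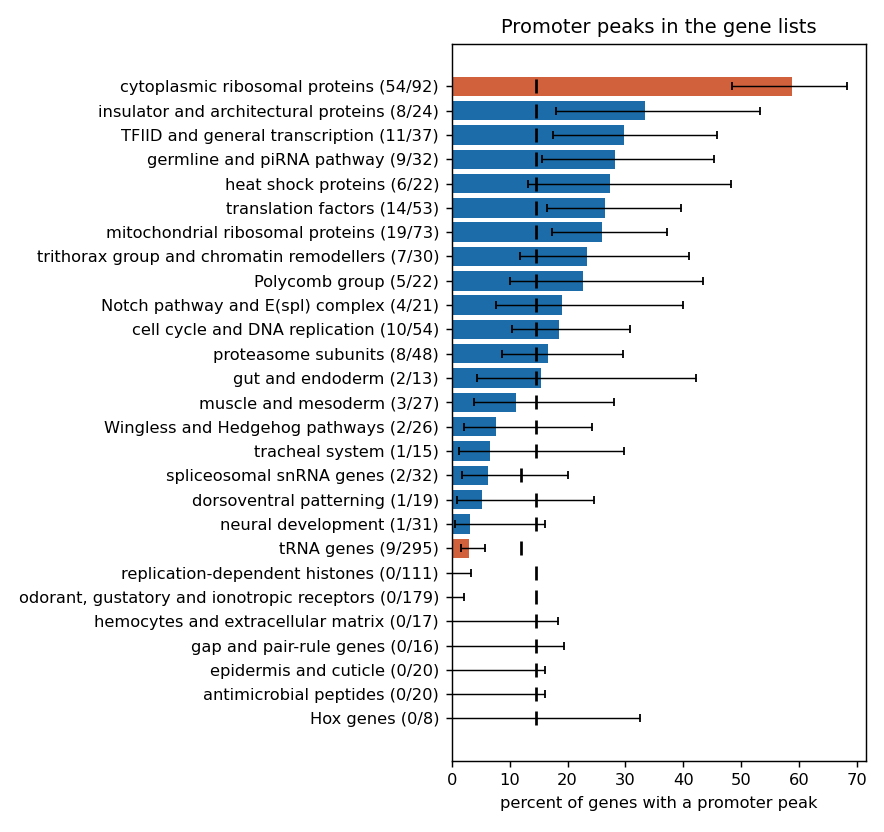
Percent of genes with a promoter peak in each list, with 95% Wilson intervals and the count of genes with a peak over all members. The black mark is the percent of the background, and lists with an adjusted p below 0.05 are orange: cytoplasmic ribosomal proteins at 58.7% and tRNA genes at 3.05%. The histone and receptor lists, at 0%, also passed.

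Divergent gene pairs were frequent among genes with a promoter peak. Of the 2040 genes, 1128 had a divergent promoter (55.3%, 53.1 to 57.4), against 2687 of 11928 genes without a peak (22.5%, 21.8 to 23.3), an odds ratio of 4.25 (Fisher exact test, p = 2.43e-186). Of the promoter peaks, 612 (39.0%) lay within 500 bp of TSSs of at least 2 genes, as at mRpS10 and Art3. With only the gene of the nearest TSS kept per peak, the share fell to 41.9% and the odds ratio to 2.10 (Fisher exact test, p = 5.04e-37).

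Summits lay in AT-rich DNA. Mean GC content was 33.7% ± 9.64 (SD, 3216 peaks) within 50 bp of the summit and 43.5% ± 9.92 in the window 300 bp away, and it was lower at the summit in 74.97% of peaks (exact sign test, p = 2.49e-210). At the 300 peaks with the highest signal it was 29.4% ± 8.53 against 44.5% ± 9.49, lower in 89.7% of peaks, and at the 2216 peaks ranked below 1000 35.2% ± 9.77 against 43.2% ± 10.3. All 36 6-mers made of A and T alone were more frequent at the summit (adjusted p below 0.05), within 425 of 2080 6-mers that were more frequent and 899 that were less frequent. Against windows of the same GC count 67 were more and 49 less frequent, and at promoter peaks against promoter windows without a peak 149 and 217. The 5 leading 6-mers were TTAAAA, AAATAT, ATTTTA, ATTTAA and TATTAA. TTAAAA was in 34.9% of summit windows and 14.7% of the others (odds ratio 3.02, exact McNemar test, adjusted p = 6.22e-73).

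**Figure D4:**
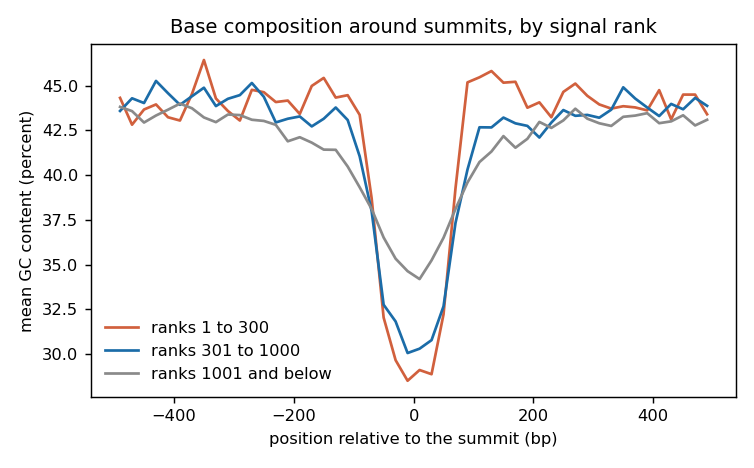
Mean GC content in bins of 20 bp around conservative summits, in percent, for the 300 peaks with the highest signal, the next 700 and the other 2216. At the summit the first group falls to 28.5% and the last to 34.2%.

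Of the 29 consensus words, 7 were more frequent at summits and 4 less frequent. The DNA replication-related element TATCGATA, the site of the promoter factor Dref, was in 1.65% of summit windows against 0.28% (odds ratio 6.18, exact McNemar test, adjusted p = 3.02e-08). The Su(Hw) word TGCATACYT was in 0.529% against 0.0622% (odds ratio 7, exact McNemar test, adjusted p = 0.00235), the core promoter word Ohler7 in 2.55% against 1.27% (2.01, adjusted p = 0.00101), the homeodomain word TAATTA in 10.2% against 5.50% (2.00, adjusted p = 9.21e-12) and the TATA word in 1.93% against 0.995% (1.92, adjusted p = 0.0075). The CA repeat (odds ratio 0.243, exact McNemar test, adjusted p = 2.25e-14), the GAGA word (0.28, adjusted p = 4.23e-11) and CACGTG (0.441, adjusted p = 0.00232) were less frequent. Some of these calls held in 1 replicate alone and not in the other. The GAGA word (odds ratio 0.189) and CACGTG (0.359) passed in replicate 2 alone and not in replicate 1 alone (0.85 and 0.704). The Su(Hw) word (4.56) and Ohler7 (2.31) passed in replicate 1 alone and not in replicate 2 alone (2.71 and 1.60). The CA repeat passed in both, at 0.618 in replicate 1 and 0.165 in replicate 2, and Ohler7 did not at an IDR of 0.001 either (1.21). The odds ratio of TATCGATA was 2.74 in replicate 1 alone and 3.35 in replicate 2 alone, and that of TAATTA 1.31 in replicate 1 alone, all past the threshold. The words AATAAAA, YCGATA and the initiator word TCAGTY passed as well, the last of them less frequent, and it passed in neither replicate alone. A further comparison took only the 1569 promoter peaks, an unpaired Fisher exact test and windows at promoters without a peak, at the same distances to a TSS, so it differs in more than the background. There 3 words were more frequent: Ohler7 (odds ratio 2.65), TAATTA (1.43) and AATAAAA (1.61). The Su(Hw) word stayed more frequent without passing (2.505, 5 against 2 windows), the TATA word (0.785) and YCGATA (0.917) turned below 1 without passing, and TATCGATA did not pass (odds ratio 1.39, 3.25% against 2.36%, Fisher exact test, adjusted p = 0.462). In an unpaired Fisher exact test of all peaks against windows of the same GC count, 6 words were more frequent: Ohler7 (odds ratio 4.65), TATCGATA (4.13), Motif1 (4.02), the CTCF word (1.69), CAGCTG (1.66) and YCGATA (1.53). The direction turned, without passing, for TAATTA (0.836), AATAAAA (0.878), the TATA word (0.883), the GAGA word (1.46) and CACGTG (1.72). The Su(Hw) word (1.55), the CA repeat (0.778) and the initiator word (0.874) kept their direction without passing. The windows of the same GC count were not matched on class of DNA. Against the windows 300 bp away, CAGCTG (0.803), the CTCF word (0.973) and Motif1 (1.52) did not pass. At promoter peaks against promoter windows they did not pass either (0.837, 1.20 and 0.873). Over 11 settings, CAGCTG passed as more frequent in 1 and as less frequent in 3. Motif1 passed as more frequent in 5 and the CTCF word in 2. Against the promoter windows the GAGA word passed (odds ratio 0.32), and the CA repeat (0.436, Fisher exact test, adjusted p = 0.0514) and the initiator word (0.737, adjusted p = 0.072) were less frequent without passing, while CACGTG was at 1.08.

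The X chromosome held 629 conservative peaks, or 26.8 per Mb, and the autosomal arms 2L, 2R, 3L and 3R 23.7 per Mb. The ratio was 1.13 (95% exact interval 1.03 to 1.23, exact binomial test, p = 0.00687). It was 0.98 (exact binomial test, p = 0.629) in the list of replicate 1 alone and 1.19 (p = 0.000436) in that of replicate 2 alone, and 1.02 (p = 0.614) in the optimal list, so the excess on X did not hold in every list. The labels do not give the sex of the embryos, so these ratios are not corrected for the copy number of X. Chromosome 4 held 5 conservative peaks and Y none. The conservative list drew on both replicates, and the ranked list of replicate 2 held only 82 peaks on chromosome 4. That of replicate 1 held 1 on Y, so these low counts do not show a lack of binding there.

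The replicates shared a part of their peaks, smaller for the longer list of replicate 1. Of 4617 peaks of replicate 1, 2162 overlapped a replicate 2 peak (46.8%, 95% Wilson interval 45.4 to 48.3), against a mean of 1.13% in random placements. Of 2721 peaks of replicate 2 on the chromosome arms, 2135 overlapped a replicate 1 peak (78.5%, 76.9 to 80.0), against 1.85%. The permutation p was 0.0099 for both, one-sided, the smallest that 100 placements can give. The placements were even along each chromosome and did not keep to promoters. This p therefore speaks only against evenly spread peaks and does not measure reproducibility. Of the conservative peaks, 65.9% overlapped a peak in the list of each replicate, 683 in replicate 1 alone, 225 in replicate 2 alone and 188 in neither. Across the 3216 conservative peaks, which are not independent replicates, the replicates' signals had a Spearman correlation of 0.644 (bootstrap interval 0.619 to 0.667) and a Pearson correlation of 0.892. These peaks were selected for reproducibility between the same 2 replicates, so the 2 values are no independent measure of agreement. Over all 90707 ranked peaks on the chromosome arms Spearman's rho was 0.252.

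Peaks found in 1 replicate lay less often at promoters. In replicate 1, 45.3% (43.3 to 47.2) of the 2455 peaks without a replicate 2 peak were at promoters, against 52.3% (50.2 to 54.4) of the 2162 shared peaks (Fisher exact test, two-sided, p = 2.02e-06). In replicate 2 the shares were 42.8% of 586 and 51.9% of 2135 (Fisher exact test, p = 0.000129). The median signal was 51.1 against 89.3 in replicate 1 and 46.0 against 75.4 in replicate 2. With promoters of 200 bp the difference in replicate 1 was smaller, -2.92 percentage points against -7.01 (Fisher exact test, p = 0.0414).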

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

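The tests of the length of the replicate 1 list, of regions left out by the authors and of words of A and T, and the comparison between draws of windows of the same GC count, were chosen after their results were seen, and the test with signal deciles after the first signal model was seen. Replicate 2 had 16 thresholded peaks on sequences outside the 7 chromosome arms, where replicate 1 had 0. They lay on 15 sequences, with a median signal of 52.7 and a maximum of 212, and count only in the total of 2737 peaks, which the ratio of list lengths and the share of chromosome 4 use. The optimal list held 2587 peaks that the conservative list lacks. Of these, 41.6% (39.7 to 43.5) were at promoters, 1302 overlapped a peak of replicate 1 and 333 a peak of replicate 2.

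Chromosome 4 differed between the replicates: it held 28 of 4617 thresholded peaks in replicate 1 and 4 of 2737 in replicate 2. The odds ratio was 4.17 (1.46 to 11.9), on the same counts that drew attention to chromosome 4, so it is no fresh test of the length of the lists. The strongest 2737 replicate 1 peaks still held 13 on chromosome 4 (odds ratio 3.26, interval 1.06 to 10.01), which argues, by a narrow margin, against weak peaks at the end of the longer list. The ranked lists hold peaks that the thresholded lists leave out, and among them replicate 2 has the longer list (86109 against 78581 peaks). The odds ratio there was 11.9 (9.51 to 14.95), which argues against both list length and regions left out after ranking. Regions left out before ranking could not be checked. Per Mb, chromosome 4 held 663 ranked peaks in replicate 1 and 61.6 in replicate 2. The arms 2L, 2R, 3L, 3R and X held 545 to 631 in replicate 1 and 581 to 688 in replicate 2. In the ranked lists the difference thus lay in few chromosome 4 peaks in replicate 2, while replicate 1 was close to its larger arms. Differences in chromosome content of the embryos or in the control reads stay open, and no biological explanation was tested.

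Positions of the same class without a peak, at the same distance to a TSS for promoters, had a mean GC content of 40.5% against 33.7%, a difference of -6.74 percentage points (bootstrap interval -7.20 to -6.27), so the general composition of such DNA is not the whole cause. An excess of AT-rich DNA in the libraries stays open and cannot be told apart. Of 5485 genes whose promoter window was as AT-rich as the median promoter summit, 18.2% (17.2 to 19.3) had a peak. Of the 8476 other genes, 12.3% had one (Fisher exact test, p = 8.48e-22). At most 37.2% of the AT-rich promoters could have had a peak, below the 50% named beforehand. Against windows of the same GC count, 67 6-mers (3.22%) were still more frequent at summits. This met the bound of at most 5% written beforehand for composition alone. In a comparison added once the 3.22% was known, 2 draws of such windows gave 0 such words between them. Draws from the same pool give about 0 after adjustment by construction, so this comparison does not decide on the bound. The 67 words themselves passed with the GC count held equal (smallest adjusted p = 3.87e-12, Fisher exact test). The class of DNA, which such windows do not match, stays open as their cause. For words of A and T alone, 6 of 36 still passed, which leaves open how far composition accounts for them.

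The lower promoter share of peaks found in 1 replicate was set against their weaker signal. In a logistic model with the log2 signal, the odds ratio for replicate 1 peaks was 0.755 (0.664 to 0.858), so signal does not account for it there, although the odds ratio without signal was 0.755 as well, because promoter location did not change with signal in that model. With signal deciles as classes it was 0.744 (0.648 to 0.854). For replicate 2 it was 0.903 (0.739 to 1.102), and with deciles 0.945 (0.766 to 1.16), against 0.696 without signal, so weaker signal may account for the difference. No biological explanation was tested.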

How the results depend on the processing

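All thresholded peaks already met a global IDR of 0.01, so the alternative at that value, chosen before the data were examined, left out nothing and shows no stability. The alternatives at an IDR of 0.001 and 0.05, with merged peaks, with windows of the same GC count and, for 6-mers, with promoter windows were chosen after seeing the data. The promoter share stayed between 36.7% and 59.1% and the divergent share between 41.9% and 65.4%, all past the threshold. The number of peaks was 5675 in the optimal list, 1822 at an IDR of 0.001 and 4935 at 0.05, and genes with a promoter peak numbered 3061 in the optimal list and 1325 at 0.001. The density ratio of X to autosomes was 1.02 in the optimal list and 1.02 at an IDR of 0.05, neither past the threshold, and 0.98 to 1.19 with 1 replicate left out. It was 1.21 at an IDR of 0.001, 1.14 with merged peaks and 1.29 per protein-coding gene, all past the threshold. Without replicate 2 it reversed to 0.98, and the cause was not tested. The rank correlation was 0.252 over all ranked peaks and 0.586 without the strongest 5%. Enriched words numbered 3 at promoter peaks against promoter windows without a peak (an unpaired test on fewer peaks), and enriched 6-mers 67 against windows of the same GC count and 149 against such promoter windows. The causes were not tested, except that stricter or looser lists hold fewer or more peaks by construction. The 4 gene lists became 3 to 6. The histone list could not be tested against genes with any ranked peak, having fewer than 5 members there. With 1 replicate left out, the number of peaks was 2721 to 4617 and of genes 1844 to 2601. Unknown read depth limits what absent peaks show. No paired analysis was possible because there is 1 group.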

Other observations

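The counts per gene, the tests of single gene lists, and the chromosome shares in this part were chosen after their values were seen, and the comparison of CAGTG with other words after its first ratio was seen, while the other tests of the 3 hypotheses were written before their values. The genes with the most conservative summits outside promoters were kirre with 11 in 394 kb, CHES-1-like with 10 in 27.0 kb, and CG1677, CG32264 and shn with 9 each. Raf and sbb held 8 each, and CG12535, Hr4 and ush 7 each. A hypothesis was that patterning and neural genes hold more such summits than other genes of their length. The 121 genes of 6 developmental lists held 32, at the 51.8th percentile of 10000 random gene sets matched on length, whose median was 31, so no excess was seen. Tracheal genes held 11 against a median of 4 (permutation test, one-sided p = 0.0435, adjusted p = 0.689) and muscle and mesoderm genes 18 against 9 (p = 0.0795, adjusted p = 0.689), and neither passed.

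A hypothesis was that ribosomal protein genes have promoter peaks because of neighbours at divergent promoters. Among genes without a divergent promoter, 30 of 56 ribosomal protein genes had a peak (53.6%) against 8.74% of 10097 others, an odds ratio of 12.1 (7.10 to 20.5). This argues against the hypothesis for head-to-head neighbours within 500 bp, while neighbours farther away or on the same strand were not set apart. Among genes with a divergent promoter, the shares were 66.7% of 36 and 29.2% of 3779.

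Among 6-mers more frequent at summits than in windows of the same GC count, the leading one was ACAGTG (7.99% against 3.42%, odds ratio 2.45, Fisher exact test, adjusted p = 3.87e-12), followed by CGATAG (4.54% against 1.55%, odds ratio 3.01). Of the 67, 6 contained CAGTG. This core was in 20.02% of summit windows and 11.7% of windows of the same GC count. It was in 16.8% of windows matched on class (Fisher exact test, p = 0.00103). At promoters it was in 19.06% of summit windows and 19.57% of matched windows. The class-matched windows were richer in GC (40.5% against 33.7%, and 40.2% against 34.3% at promoters). The values at promoters therefore do not show that an excess is lacking. A hypothesis was that CAGTG lies where the protein is bound. Per position, windows with CAGTG within 15 bp of the summit were 0.613 times as frequent as windows with it at 33 bp or more (exact McNemar test, p = 2.1e-08), but GC content was lower near the summit (32.9% against 34.6%), so this ratio alone decides nothing. Among the 159 other 5-mers with as many G and C the median ratio was 0.924, and CAGTG stood at the 1.89th percentile, which argues against the hypothesis.

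The ranked lists differed between replicates on other chromosomes too. Y held 1 ranked peak in replicate 1 and 107 in replicate 2, and X took 18.8% of the ranked peaks in replicate 1 and 15.8% in replicate 2. In the thresholded lists the order for X was the reverse, 17.3% in replicate 1 and 20.2% in replicate 2.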
